A study of Mus musculus with 8 samples.

How the data were processed

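The series holds 8 one-colour Illumina arrays of sorted mouse CD4 T cells from mixed bone marrow chimeras on the C57BL/6 background, 2 each for WT Treg, NIKtg Treg, WT Tconv and NIKtg Tconv. Per the labels' protocols, cells were sorted from chimeras more than 8 weeks after reconstitution, RNA was extracted with a column kit, and biotin-labelled cRNA was prepared with an amplification kit for Illumina arrays. The submitters' processing notes name GenomeStudio 2010.1. A genome build is not given in the sources used here, so no coordinates are printed.

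The authors deposited unnormalized probe intensities on a linear scale, with no background subtracted, since the lowest value on each array lay between 63.9 and 74.4. Per the file headers, each intensity is followed by a detection p-value, which moves in steps that imply 798 negative control probes. The authors also deposited a table of normalized intensities of the same arrays. These are on a linear scale, with medians between 118.6 and 118.8 on the 8 arrays and no centring at 0. The nearly equal sorted values point to quantile normalization, which no source used here states. Each column ranked the probes as the unnormalized column of the same array did (Spearman rho of 1 on each). That table was used as an alternative. The log2 values were computed here.

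Probes were named through the platform annotation, which gave 1 gene symbol for 23978 of 25697 probes, several for 0, and did not list 1719. Updating symbols through Entrez identifiers changed 0 symbols, and 16 symbols had no matching identifier. No 2 arrays shared identical values. Intensities were corrected for background with limma 3.58.1 in R 4.3.3 (nec, negative controls inferred from the detection p, offset 16), quantile normalized and put on the log2 scale. Probes with a detection p under 0.01 on at least 2 arrays were kept. These were 11526 probes, 10819 of them named and 707 unnamed, and the unnamed ones stayed out of gene counts. For each gene the probe with the highest mean over the 8 arrays was used, which gave 7926 genes, 2087 of them with several kept probes. Depth of reads has no counterpart here, and the number of arrays limits the precision.

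A linear model with 1 coefficient per group was fitted to all 8 arrays with limma (lmFit and eBayes, two-sided), which left 4 residual degrees of freedom, with 3.55 prior degrees of freedom and a prior SD of 0.134 on the log2 scale. Contrasts were NIKtg minus WT in Treg and in Tconv, the difference between these effects (Treg minus Tconv), and Treg minus Tconv in WT and in NIKtg cells. P-values were adjusted by Benjamini and Hochberg over the 7926 genes of a contrast, with a threshold of 0.05. Each adjusted p in the text comes from limma, from its moderated test for genes and from camera for lists. The replicate numbers in the labels were not used as pairs.

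A gene detected on neither array of its dimmer group and on at least 1 of the brighter group has only a bound there. Its fold is given as "at least N-fold", a bound for detection only that takes no account of the spread between replicates. The brighter group's mean over its 2 arrays was set against the dimmer group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal, on normalized log2 values. No fold is given where that bound lay under 1 or where both groups were below detection. Differences between the NIK effects are fitted values and are not bounds. Medians of lists were also computed with such genes at their bounds. A named gene detected on 1 of the 2 arrays of its dimmer group is also printed as such a bound. This was decided after the data were seen, and the medians with bounds do not cover it.

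The groups, the tests, the rule for named genes, the 25 gene lists and the alternatives, apart from the calls among genes with several probes, were fixed before the data were examined. Named genes were Map3k14, Foxp3, Thy1 and Cd4. In each NIK comparison they were also the 10 largest increases and 10 largest decreases among genes past the threshold with both arrays of one group above both of the other (5 and 5 in the other comparisons). Then followed up to 4 members per list past the threshold with the smallest adjusted p and, in the NIK comparisons, up to 2 not past it with the largest change. A subset of these is printed.

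The lists were Treg signature genes, genes low in Treg, NF-kB pathway components, NF-kB target genes, the TNF and TNF receptor family with costimulation, effector cytokines, helper lineage transcription factors, effector and memory T cell genes, naive T cell genes, inhibitory receptors and exhaustion, follicular helper genes, proliferation genes, glycolysis genes, interferon response genes, T cell receptor immediate early genes, apoptosis regulators, T cell receptor signalling genes, chemokine receptors and homing molecules, suppressor function mediators, heat shock and stress genes, B cell markers, myeloid and dendritic cell markers, CD8 and NK cell markers, erythroid and platelet markers, and ribosomal protein genes. Apart from the ribosomal genes they held 452 names, of which 398 were on the annotation and 311 were tested. Some genes stand in several lists. Lists were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, each adjusted over the 25 lists. A higher adjusted p with an estimated correlation does not by itself show correlated genes, since it also rose for lists whose estimate lay under 0.01.

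The gene-level and list steps were tested on simulated data with the same 7926 genes for NIKtg Treg against WT Treg, with 200 genes changed. The steps recovered 90% of 2-fold and 99% of 4-fold changes, with 7 false among 196 calls and 0 calls in the unchanged Tconv comparison. Camera called 0 of 100 random lists. For a list with each member shifted equally its adjusted p was 3.9e-21, and 0.038 with an estimated correlation. Genes were simulated independently of each other, so the 0 calls cannot show how camera treats correlated lists, and the rise to 0.038 arose without such correlation. The data also held more calls than the simulation, from 19.9% to 39.9% of genes per comparison.

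Alternatives were no background correction, median centring in place of quantile normalization, an offset of 50, the authors' deposited normalized intensities, no filter, detection on all 8 arrays, a detection p under 0.05, the mean of a gene's probes, every probe as its own feature, only the groups compared, eBayes with trend and robust set, array weights, the replicate number as a fixed or random block, each array left out in turn, the other set tests, and a 2-fold minimum. A slide block was not run, since the files give no slide. Calls among genes with several probes, by their brightest probe or by every probe in 1 direction, were added after seeing that probes of a gene disagreed.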

Results

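RNA was measured in CD4 T cells that developed in mixed bone marrow chimeras. In such animals, marrow from 2 donors rebuilds the blood of an irradiated recipient, so that WT and transgenic cells mature side by side in the same host. Donor cells of the first kind carried a transgene for NIK, the kinase encoded by Map3k14, which starts the noncanonical NF-kB pathway. The transgene was placed at the ROSA26 locus and combined with Cre recombinase driven by the CD4 promoter. WT donor cells carried the Thy1.1 surface allele. Cells of either origin carried a red fluorescent reporter of Foxp3, the transcription factor that defines regulatory T cells (Treg). Cells were sorted as reporter-positive Treg or reporter-negative conventional T cells (Tconv). WT cells were gated as Thy1.1-positive and GFP-negative, and NIKtg cells as Thy1.1-negative and GFP-positive. NIKtg and WT cells thus differed in GFP and the Thy1 allele besides the transgene, and no group is labelled as carrying Cre or GFP without it. An effect of NIK below names the difference between NIKtg and WT arrays, in which these causes cannot be told apart. Each of the 4 groups (WT Treg, NIKtg Treg, WT Tconv and NIKtg Tconv) held 2 arrays.

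The 8 arrays measured 25697 probes, of which between 9826 (NIKtg Treg 2) and 10794 (NIKtg Tconv 1) were detected per array at a detection p under 0.01. Mean unnormalized intensity was lowest on the NIKtg Treg arrays, at 461.1 and 473.6, and highest on NIKtg Tconv 2, at 776.8. After background correction and quantile normalization, 7926 genes were tested. Across genes, arrays of 1 group correlated at r between 0.9889 and 0.9942, and arrays of different groups at r between 0.9231 and 0.9731. The number of arrays limits the precision of every value below. An "at least" fold is a bound for detection only and takes no account of the spread between replicates. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

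Foxp3 separated the sorts, with log2 intensities of 13.48 and 13.57 in WT Treg, 13.19 and 13.36 in NIKtg Treg, 8.05 and 8.82 in WT Tconv, and 6.07 and 7.01 in NIKtg Tconv. Map3k14 was not raised on the arrays labelled NIKtg. Its log2 fold change was 0.09 (SE 0.11, adjusted p = 0.579, n = 2 arrays per group, limma) in Treg, and in Tconv it fell by 0.52 (SE 0.11, adjusted p = 0.0102). The Tconv call was lost without NIKtg Tconv 1 (adjusted p = 0.0586) or without WT Tconv 1 (adjusted p = 0.0616). Map3k14 was read by 1 probe whose place in the transcript is not given in the sources used here, so that probe cannot tell whether transgene RNA was measured, and NIKtg names the label of an array throughout. Nfkb2, which encodes the p100 precursor that NIK acts on, rose by 1.02 (SE 0.11, adjusted p = 0.00198) in Treg and by 1.46 (SE 0.11, adjusted p = 0.000291) in Tconv, on each NIKtg array above each WT array. Relb, the partner of the processed Nfkb2 product and a gene named after its values were seen, gave 0.25 (SE 0.10, adjusted p = 0.12) and 0.24 (SE 0.10, adjusted p = 0.11), which did not pass. Thy1, whose alleles served the sort, differed by 0.24 (adjusted p = 0.249) in Treg and -0.03 (adjusted p = 0.876) in Tconv. Cd4 differed by -0.06 (adjusted p = 0.866) and -0.36 (adjusted p = 0.262).

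**Figure D1:**
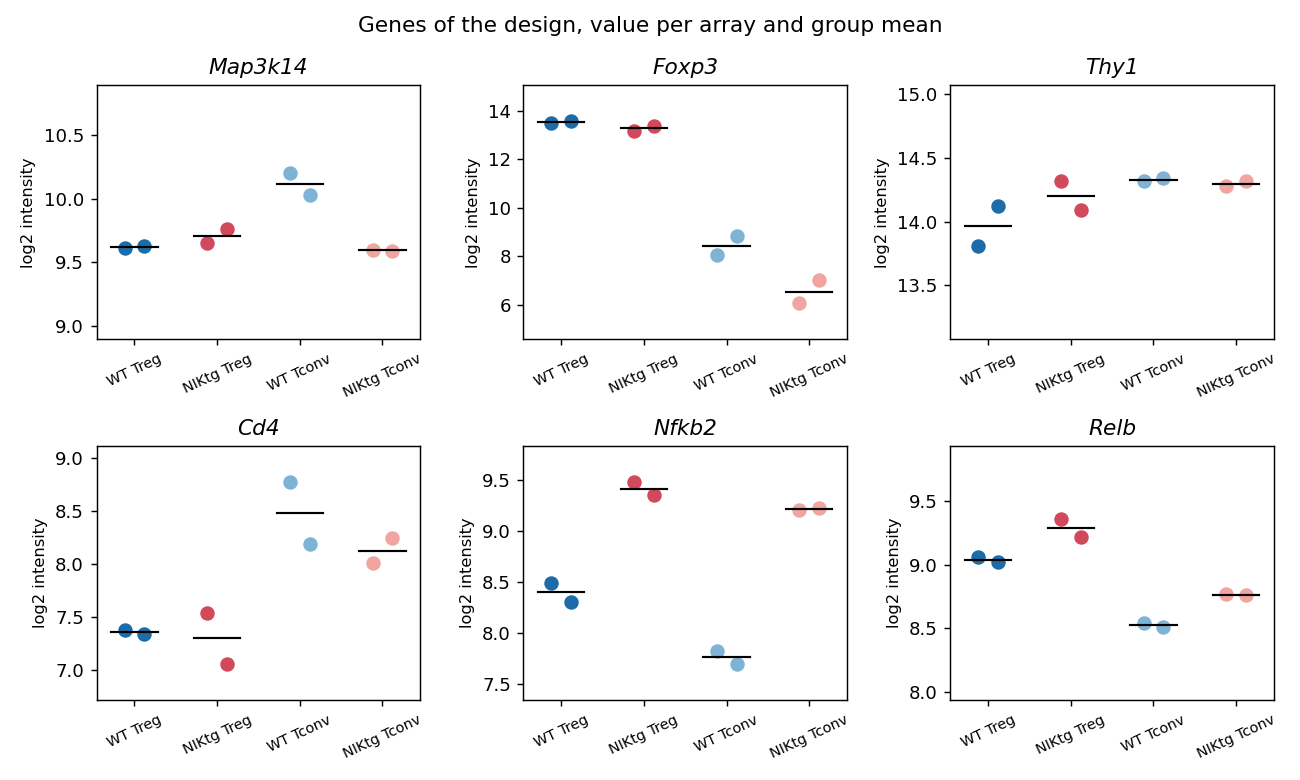
Normalized log2 intensity of 6 genes (vertical axes, each with its own range) on the 8 arrays, 1 point per array, with a line at each group's mean of 2 arrays. Nfkb2 lies above 9.2 on the 4 NIKtg arrays and below 8.5 on the 4 WT arrays, while Map3k14 shows no such step.

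WT Treg and WT Tconv were compared as the reference difference between the sorted subsets. Foxp3 was 5.09 log2 units higher in WT Treg (SE 0.33, adjusted p = 8.54e-05, n = 2 arrays per group), Itgae, an integrin of epithelium-homing lymphocytes, 4.91 higher (SE 0.23, adjusted p = 2.75e-05), and the activation marker Cd83 4.47 higher (SE 0.24, adjusted p = 4.15e-05). Gbp2b, an interferon-inducible GTPase, was at least 17.8-fold higher, and Gm3696 at least 11.7-fold higher. Pdlim4, an actin-associated LIM protein, was at least 78.1-fold lower in WT Treg, the channel gene Aqp9 at least 12.6-fold lower and Lypd6b at least 11.9-fold lower. The NK receptor gene Klrd1 was at least 21.8-fold lower in WT Treg, and the chemokine receptor gene Cxcr6 was lower too (-4.40, SE 0.39). In all, 1906 of 7926 genes differed at an adjusted p under 0.05 (limma), 882 higher and 1024 lower in WT Treg (46.3% higher). Of these, 568 differed at least 2-fold, with the majority turned, 356 higher and 212 lower. Leaving out WT Treg 1, WT Treg 2 or WT Tconv 1 gave 994, 999 and 1031 genes, 53.3%, 52% and 54.2% of them higher, and without WT Tconv 2 50.5% were higher. By a setting chosen after the data were seen, which kept genes with several probes only when every probe passed in 1 direction, 66.1% of 221 genes were higher.

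Among 26 tested Treg signature genes, 23 were higher in WT Treg and none lower (26 and 0 adjusted over the list alone), with a median log2 fold change of 2.69. Swap70 was 3.38 higher (SE 0.11, adjusted p = 1.61e-05), the costimulatory receptor gene Tnfrsf4 3.18 (SE 0.14), and the inhibitory receptor gene Ctla4 3.21 (SE 0.15). Suppressor function mediators were higher for 7 of 10 (9 adjusted over the list alone), among them the cytokine subunit gene Ebi3 (3.24, SE 0.19) and the ectonucleotidase gene Nt5e (1.96, SE 0.11). Camera's adjusted p was 8.74e-24 for the Treg signature and 4.97e-07 for the suppressor mediators, and for each it was an adjusted p of 0.0868 with an estimated correlation. NF-kB target genes were higher for 15 and lower for 1 of 31 (18 and 2 adjusted over the list alone), NF-kB pathway components for 9 and 1 of 20 (10 and 1 adjusted over the list alone), and genes of the TNF and TNF receptor family and costimulation for 11 and 1 of 20 (11 and 2 adjusted over the list alone). Examples were Tnfrsf9 (2.97, SE 0.18), the costimulatory ligand gene Cd86 (3.01, SE 0.22), Irf4, a transcription factor of activated lymphocytes (1.67, SE 0.18), and Traf1 (1.00, SE 0.12), which stands in both NF-kB lists. Camera adjusted p values of the NF-kB target, pathway component and TNF family lists were 6.08e-07, 9e-04 and 1.51e-05. With an estimated correlation the adjusted p values were 0.0885, 0.096 and 0.096. Naive T cell genes were lower for 10 of 17 and higher for none (13 and 0 adjusted over the list alone), including Dapl1 (-3.49, SE 0.17) and the quiescence factor Klf2 (-1.20, SE 0.10), with a camera adjusted p of 2.58e-06 and an adjusted p of 0.208 with an estimated correlation.

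CD8 and NK cell markers were lower in WT Treg for 6 of 7 (6 adjusted over the list alone), among them Klrb1c, at least 6.11-fold lower, and the chemokine gene Xcl1 (-2.99, SE 0.37), with a camera adjusted p of 0.00152 and an adjusted p of 0.096 with an estimated correlation. With genes below detection at their bounds, that list's median changed from -1.98 to -0.96, and that of the inhibitory receptors from 0.71 to 0.55. B cell markers were higher for 6 of 10 (7 adjusted over the list alone). Cd79b was 2.72 higher (SE 0.11), Fcmr 2.17 (SE 0.21) and Cd74, the class II invariant chain, 1.95 (SE 0.16), at a camera adjusted p of 1.51e-05 and an adjusted p of 0.121 with an estimated correlation. Another 7 of the 25 lists passed camera in this comparison. Apoptosis regulators (adjusted p = 0.00421), inhibitory receptors (0.0146), follicular helper genes (0.0228), chemokine receptors (0.0377), glycolysis genes (0.0468) and myeloid markers (0.0468) shifted upward, and genes low in Treg (0.0468) shifted downward. With an estimated correlation their adjusted p values lay between 0.096 and 0.422. The follicular helper list was lost without WT Tconv 2 (adjusted p = 0.165), the chemokine receptor list without WT Tconv 1 (0.0522) and with median centring (0.0584), and the myeloid list without WT Tconv 2 (0.194) or WT Treg 1 (0.112). The list of genes low in Treg was lost without WT Tconv 2 (0.109), NIKtg Treg 1 (0.0615) or NIKtg Treg 2 (0.0615), and with the replicate block (0.0678). The glycolysis list was lost without WT Treg 1 (0.0684), NIKtg Tconv 1 (0.0676), NIKtg Tconv 2 (0.0676), NIKtg Treg 1 (0.0615) or NIKtg Treg 2 (0.0615), and with the replicate block (0.0647), median centring (0.0996) and the mean of probes (0.0674). Among genes detected on all 8 arrays the glycolysis (0.0762), chemokine receptor (0.0762), CD8 and NK cell (0.0857) and myeloid (0.0983) lists missed the threshold. Median, mean and test differed in sign, among lists that did not pass, for effector cytokines, helper lineage factors, effector and memory genes, interferon response genes, immediate early genes, T cell receptor signalling genes and ribosomal protein genes.

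The next comparison asked how NIKtg Treg differed from WT Treg. On the arrays labelled NIKtg Treg, many Treg signature and effector T cell genes fell, while Foxp3 itself did not pass (log2 fold change -0.25, SE 0.33, adjusted p = 0.618, n = 2 arrays per group). The cytokine gene Il10 was at least 2.66-fold lower (adjusted p = 0.0025), the chemokine receptor gene Cxcr3 fell by 2.78 (SE 0.22, adjusted p = 0.000804), and the cytokine gene Ifng was at least 6.2-fold lower (adjusted p = 0.00347). Tbx21, which encodes the T helper transcription factor T-bet, was at least 3.08-fold lower (adjusted p = 0.00217), whereas Eomes, its T-box relative, rose by 3.10 (SE 0.21, adjusted p = 0.000501). The inhibitory receptor gene Klrg1 was at least 9.78-fold lower (adjusted p = 0.0168), a call lost without NIKtg Treg 1 (adjusted p = 0.079), WT Treg 1 (0.0574) or WT Treg 2 (0.0941), and with trend and robust set (0.0664).

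Among the largest increases, Myh7 and Tnni3, a myosin heavy chain and a troponin of heart muscle, were at least 7.64-fold (adjusted p = 0.000501) and at least 5.58-fold higher (adjusted p = 0.00217), and the sarcomeric actinin gene Actn2 rose by 3.18 (SE 0.22, adjusted p = 0.000548). The lipocalin gene Lcn10 was at least 7.87-fold higher, Eef1a2, a tissue-restricted translation elongation factor, at least 5.32-fold, Tex35 at least 4.85-fold and the calcium-binding Kcnip3 at least 4.78-fold. Igsf3 rose by 3.30 (SE 0.17) and Tmem176b by 3.20 (SE 0.33). The largest decreases also included the amino acid transporter gene Slc7a10 (at least 5.33-fold), the sodium-calcium exchanger gene Slc24a3 (at least 4.4-fold), the microtubule-associated Map2 (at least 4.36-fold), Ttc39c (at least 6.02-fold) and Cc2d2a (at least 2.48-fold). In total 1575 of 7926 genes changed at an adjusted p under 0.05 (limma), 826 higher and 749 lower, and 422 of them changed at least 2-fold, 143 higher and 279 lower. The count was 506 without WT Treg 1, 566 without WT Treg 2 and 620 without NIKtg Treg 1, and 43.9%, 47% and 42.9% of these genes were higher, against 52.4% with all arrays. That share was 47.3% with the mean of probes, 44% with every probe as its own feature, 49.6% in the fit to only the groups compared, and 28.6% of 133 genes with several probes that all passed in 1 direction.

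Of 26 Treg signature genes, 14 fell and none rose (16 and 0 adjusted over the list alone), with a median of -0.76. Ccr8, a chemokine receptor of Treg, was at least 1.79-fold lower, Nt5e fell by 1.09 (SE 0.11, adjusted p = 0.00162), as did the costimulatory receptor gene Icos (-1.02, SE 0.14, adjusted p = 0.0039). Izumo1r (-0.69, adjusted p = 0.0992) and Ikzf2 (-0.57, adjusted p = 0.0621) did not pass. Suppressor function mediators fell for 5 of 10 (7 adjusted over the list alone), Ctla4, Il10, Ebi3, Nt5e and Fgl2, each of which is also in the Treg signature list. The call of Ebi3 was lost without NIKtg Treg 1 (adjusted p = 0.0542) or WT Treg 2 (0.0631). Ctla4 fell by 0.97 (SE 0.15, adjusted p = 0.00639), and Lag3 gave -1.79 (SE 0.66, adjusted p = 0.0967). In the TNF and TNF receptor family and costimulation list, 10 of 20 fell and 1 rose (11 and 2 adjusted over the list alone), with Tnfrsf9 falling by 1.18 (SE 0.18, adjusted p = 0.00598). Among helper lineage transcription factors 8 of 15 fell and 1, Eomes, rose (8 and 2 adjusted over the list alone). Batf fell by 1.93 (SE 0.17, adjusted p = 0.00122), as did Nfil3 (-2.34, SE 0.26, adjusted p = 0.00198). Follicular helper genes fell for 6 of 13 (6 adjusted over the list alone), including Sh2d1a, a signalling adaptor of SLAM receptors, which fell by 1.00 (SE 0.12), and Maf, at least 1.58-fold lower. Chemokine receptors and homing molecules fell for 7 and rose for 1 of 14 (7 and 2 adjusted over the list alone). The integrin gene Itgb1 fell by 2.06 (SE 0.14, adjusted p = 0.000501), as did the adhesion receptor gene Cd44 (-1.21, SE 0.16). Camera gave adjusted p values of 9.22e-09 for the Treg signature, 0.000661 for the suppressor mediators, 0.00054 for the TNF family, 0.00942 for the helper factors, 0.00149 for the follicular genes and 0.00269 for the chemokine receptors. With an estimated correlation the adjusted p of each of these 6 lists was 0.162. That estimate was -0.0573 for the suppressor mediators, -0.0367 for the follicular genes and -0.0296 for the helper factors, below the preset 0.01. A higher correlation between genes therefore does not account for the loss of these. It was above the preset for the Treg signature (0.168), the TNF family (0.062) and the chemokine receptors (0.0289). With genes below detection set to their bounds, the medians of the TNF family and follicular lists changed from -0.57 to -0.40 and from -0.69 to -0.35, and those of the effector cytokine, proliferation, and erythroid and platelet lists from -0.50 to -0.13, from -0.33 to -0.23 and from -1.19 to -0.15.

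Effector and memory T cell genes fell for 8 and rose for 2 of 25 (8 and 2 adjusted over the list alone), with Lgals3 at -1.30 (SE 0.16), and effector cytokines fell for 3 of 8 (3 adjusted over the list alone), with the growth factor gene Csf1 at least 3.62-fold lower. Their camera adjusted p values were 0.00233 and 0.0114, and the adjusted p values with an estimated correlation were 0.324 and 0.196. Proliferation genes fell for 9 and rose for 2 of 24 (11 and 2 adjusted over the list alone). The topoisomerase gene Top2a fell by 0.97 (SE 0.15), as did the nucleotide synthesis gene Tyms (-1.14, SE 0.18), and the mitotic kinase gene Cdk1 was at least 1.47-fold lower, at a camera adjusted p of 0.00233 and an adjusted p of 0.268 with an estimated correlation. T cell receptor signalling genes fell for 5 of 20 (6 adjusted over the list alone), including the kinase gene Fyn (-1.97, SE 0.25). Cd247, the receptor zeta chain, read -2.38 on its brightest probe but 0.65 and 0.39 on its other probes. NF-kB target genes fell for 7 and rose for 1 of 31 (9 and 3 adjusted over the list alone). Cd83 fell by 2.03 (SE 0.24), as did Irf4 (-1.37, SE 0.18), the chemokine gene Cxcl10 was at least 2.92-fold lower, and Nfkb2 was the gene that rose. Their camera adjusted p values were 0.0078 and 0.026, and with an estimated correlation the adjusted p values were 0.184 and 0.252. The signalling list was lost with median centring (adjusted p = 0.0988). The NF-kB target list was lost with median centring (0.0781), a detection p under 0.05 (0.0524), the mean of probes (0.0537), and without NIKtg Treg 2 (0.06) or WT Treg 2 (0.0642). The cytokine list was lost among genes detected on all 8 arrays (0.734).

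NF-kB pathway components gave 1 higher and 1 lower of 20 (1 and 1 adjusted over the list alone, camera adjusted p = 0.497), the lower being the adaptor gene Traf5, at least 1.97-fold. Glycolysis genes fell for 4 of 16 (4 adjusted over the list alone, camera adjusted p = 0.218), with Hif1a, the hypoxia-response factor, at -1.89 (SE 0.20) and Pfkp at -1.69 (SE 0.24). Naive T cell genes rose for 3 and fell for 1 of 17 (3 and 1 adjusted over the list alone, camera adjusted p = 0.102), with Dapl1 at 1.27 (SE 0.17) and Klf2 at 0.66 (SE 0.10), and the interleukin receptor gene Il6ra at -1.76 (SE 0.27). Genes low in Treg rose for 2 of 9 (2 adjusted over the list alone, camera adjusted p = 0.135). Immediate early genes rose for 3 and fell for 1 of 16 (5 and 2 adjusted over the list alone, camera adjusted p = 0.562), with Jun at 1.02 (SE 0.14) and Egr2 at -1.76 (SE 0.22). Interferon response genes gave 2 higher and 2 lower of 21 (2 and 2 adjusted over the list alone, camera adjusted p = 0.811), inhibitory receptors 2 lower of 9 (2 adjusted over the list alone, 0.0973), apoptosis regulators 3 higher and 4 lower of 17 (4 and 4 adjusted over the list alone, 0.863), heat shock and stress genes 2 lower of 14 (2 adjusted over the list alone, 0.18), and ribosomal protein genes 4 higher and 1 lower of 52 (4 and 0 adjusted over the list alone, 0.473). Median, mean and test differed in sign for glycolysis genes, interferon response genes and apoptosis regulators.

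Of 10 B cell markers, 5 rose and 2 fell in NIKtg Treg (5 and 3 adjusted over the list alone, camera adjusted p = 0.165). The class II genes H2-Eb1, H2-Ab1 and H2-Aa rose by 2.40 (SE 0.20), 1.73 (SE 0.16) and 1.69 (SE 0.14), and Ly6d was at least 3.43-fold higher. Myeloid and dendritic cell markers fell for 4 of 9 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.102), including the Fc receptor chain gene Fcer1g, at least 2.98-fold lower, and the macrophage marker Adgre1, at least 1.95-fold lower. CD8 and NK cell markers rose for 1 of 7, Eomes (1 adjusted over the list alone, camera adjusted p = 0.437). Erythroid and platelet markers fell for 2 of 3 (2 adjusted over the list alone), Car2 and the globin gene Hba-a1, at a camera adjusted p of 0.0396 and an adjusted p of 0.214 with an estimated correlation. That list was lost without NIKtg Treg 2 (adjusted p = 0.133), WT Treg 2 (0.0642), WT Tconv 1 (0.0546) or WT Tconv 2 (0.0546), and with the mean of probes (0.0623), median centring (0.0752), no background correction (0.0573) and an offset of 50 (0.0551). The call of Hba-a1 was lost without WT Treg 2 (adjusted p = 0.167), NIKtg Treg 1 (0.168), WT Tconv 1 or 2 (0.0529 for each), or NIKtg Tconv 1 or 2 (0.0666 for each), without a filter (0.0621) and in the fit to only the groups compared (0.0984). Fry, which tests whether a list moves on balance in 1 direction without comparing it with other genes, passed for 20 of the 25 lists.

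The same comparison was made in Tconv. On the arrays labelled NIKtg Tconv the granzyme gene Gzmk was at least 80.8-fold higher (adjusted p = 4.23e-05, n = 2 arrays per group), Eomes rose by 5.61 (SE 0.21, adjusted p = 1.48e-05), the granzyme gene Gzmm by 5.37 (SE 0.30, adjusted p = 6.69e-05) and the chemokine gene Ccl4 by 4.68 (SE 0.25, adjusted p = 6.18e-05). Ccl3, a related chemokine gene, was at least 12.7-fold higher (adjusted p = 0.000164). The actin-severing Scin was at least 31.6-fold higher, Serpina12 at least 27.3-fold, Kcnip3 at least 21.8-fold, the calcium sensor gene Ncald at least 12.4-fold, and the integrin gene Itgad rose by 4.30 (SE 0.54). The largest decreases were of the helper cytokine gene Il4 (at least 9.38-fold, adjusted p = 0.000555), Aqp9 (at least 13-fold), the matrix protease gene Mmp9 (at least 10.9-fold), Nacc2 (at least 10.6-fold), Lrrc75b (at least 7.9-fold) and Klrb1c (at least 6.33-fold). Igfbp4 fell by 3.16 (SE 0.40), as did Plac8 (-3.13, SE 0.38), Pdlim4 (-3.05, SE 0.32) and Timp2 (-2.94, SE 0.31). Foxp3, already low in this gate, fell by 1.89 (SE 0.33, adjusted p = 0.0054). In total 2384 genes changed (limma), 1023 higher and 1361 lower (42.9% higher), and 661 of them changed at least 2-fold, 340 higher and 321 lower. Among 288 genes with several probes that all passed in 1 direction, 58.7% were higher, so the majority turned. The count was 1183 without WT Tconv 1, 964 without NIKtg Tconv 1 and 1484 without NIKtg Tconv 2.

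NF-kB target genes rose for 12 and fell for 3 of 31 (12 and 3 adjusted over the list alone), and NF-kB pathway components rose for 6 and fell for 2 of 20 (7 and 2 adjusted over the list alone). Traf1, an adaptor of TNF receptors, rose by 1.53 (SE 0.12, adjusted p = 0.00027), and Tnfaip3, a feedback inhibitor of the pathway, by 0.93 (SE 0.14, adjusted p = 0.00326). Both genes, like Nfkb2, count in both NF-kB lists, so the rises of these lists are not independent. The TNF and TNF receptor family and costimulation list rose for 8 and fell for 1 of 20 (10 and 1 adjusted over the list alone). The death receptor gene Fas rose by 1.05 (SE 0.12), the RANK ligand gene Tnfsf11 by 1.45 (SE 0.15), Cd80 was at least 1.72-fold higher, and Icos fell by 0.90 (SE 0.14). Proliferation genes rose for 11 and fell for 1 of 24 (15 and 1 adjusted over the list alone), with Tk1 at 1.75 (SE 0.19), Tyms at 1.61 (SE 0.18), Top2a at 1.40 (SE 0.15) and Cdk1 at least 3.2-fold higher. T cell receptor signalling genes rose for 7 and fell for 1 of 20 (9 and 1 adjusted over the list alone), including Fyn (1.97, SE 0.25, but 0.08 on its other kept probe), Themis (1.14, SE 0.16) and the phosphatase gene Ptpn22 (1.07, SE 0.13). Cd247, also counted as a rise, read 1.49 on its brightest probe but 0.14 and 0.13 on its other probes. Camera adjusted p values were 2.73e-05, 0.0104, 0.00408, 1.82e-05 and 0.0107 for these 5 lists in order. With an estimated correlation the adjusted p of each was 0.326. With genes below detection at their bounds, the median of the TNF family changed from 0.34 to 0.22.

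Effector and memory T cell genes rose for 11 and fell for 4 of 25 (11 and 4 adjusted over the list alone), with the annexin gene Anxa2 at 1.78 (SE 0.14), S100a10 at 0.83 (SE 0.10) and Lgals3 at -1.67 (SE 0.16). The camera adjusted p was 0.0104, and it was an adjusted p of 0.562 with an estimated correlation, 0.0518 without WT Tconv 1 and 0.0578 among genes detected on all 8 arrays, and with bounds the list's median changed from 0.47 to 0.36. Naive T cell genes fell for 13 of 17 and rose for none (14 and 1 adjusted over the list alone). The lymph node homing receptor gene Ccr7 fell by 1.94 (SE 0.24, adjusted p = 0.00142), as did Foxo1 (-1.35, SE 0.14, adjusted p = 0.000734), a transcription factor of naive T cell maintenance, and Ly6c1 (-2.66, SE 0.25, adjusted p = 0.000555). The list's camera adjusted p was 5.04e-05 and its adjusted p with an estimated correlation 0.496. Interferon response genes fell for 8 of 21 (8 adjusted over the list alone), including the immunity-related GTPase gene Igtp (-1.68, SE 0.17), Oasl1 (-1.38, SE 0.19) and the nucleic acid sensor gene Zbp1 (-0.99, SE 0.15). That camera adjusted p was 0.0272, with an adjusted p of 0.645 with an estimated correlation. The call was lost without WT Tconv 1 (0.114), without NIKtg Tconv 2 (0.106) and with the mean of probes (0.102).

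Treg signature genes went both ways in Tconv, with 6 of 26 higher and 10 lower (6 and 11 adjusted over the list alone, camera adjusted p = 0.744). Swap70 rose by 0.99 (SE 0.11), while the semaphorin receptor gene Nrp1 fell by 2.89 (SE 0.25), as did Gpr83 (-2.44, SE 0.33) and the cytokine signalling inhibitor gene Socs2 (-2.35, SE 0.28). Il10 was at least 3-fold higher (adjusted p = 0.00436). Follicular helper genes rose for 4 and fell for 5 of 13 (4 and 6 adjusted over the list alone, camera adjusted p = 0.969), with the follicle-homing receptor gene Cxcr5 at 3.22 (SE 0.14, adjusted p = 2.71e-05), Sh2d1a at 1.76 (SE 0.12) and Slamf6 at 1.29 (SE 0.15). Helper lineage transcription factors rose for 3 and fell for 5 of 15 (3 and 6 adjusted over the list alone, camera adjusted p = 0.938), with Batf at 1.83 (SE 0.17) and Zbtb7b, which directs CD4 lineage choice, at least 1.79-fold lower. The inhibitory receptor gene Havcr2 was at least 5.45-fold higher and Btla fell by 0.70 (SE 0.12), in a list with 3 higher and 2 lower of 9 (3 and 3 adjusted over the list alone, camera adjusted p = 0.437). Genes low in Treg fell for 5 and rose for 1 of 9 (5 and 2 adjusted over the list alone, camera adjusted p = 0.448), with Satb1 at -2.14 (SE 0.40). Immediate early genes fell for 5 and rose for 2 of 16 (5 and 2 adjusted over the list alone, 0.466), with Fos at -1.11 (SE 0.12) and Nr4a2 at least 2.79-fold higher. Glycolysis genes gave 4 higher and 4 lower of 16 (5 and 5 adjusted over the list alone, 0.555), with Hk2 at 1.33 (SE 0.22) and Pdk1 at -1.44 (SE 0.19). Effector cytokines gave 1 higher and 2 lower of 8 (1 and 4 adjusted over the list alone, 0.448), apoptosis regulators 6 and 3 of 17 (7 and 4 adjusted over the list alone, 0.144), chemokine receptors 5 and 4 of 14 (5 and 4 adjusted over the list alone, 0.555), suppressor mediators 1 and 2 of 10 (1 and 5 adjusted over the list alone, 0.81), stress genes 1 and 1 of 14 (1 and 1 adjusted over the list alone, 0.555), and ribosomal protein genes 2 and 1 of 52 (0 and 0 adjusted over the list alone, 0.744).

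Beside these groups, B cell markers rose for 5 and fell for 2 of 10 (5 and 2 adjusted over the list alone), with Cd74 at 1.70 (SE 0.16), Cd22 at 2.79 (SE 0.34) and H2-Eb1 at 1.53 (SE 0.20). The camera adjusted p was 0.0354, the adjusted p with an estimated correlation 0.496, and the call was lost without NIKtg Tconv 1 (0.0595) or WT Tconv 2 (0.152). Myeloid and dendritic cell markers fell for 4 of 9 (4 adjusted over the list alone, camera adjusted p = 0.144), with Fcer1g at -1.36 (SE 0.24). CD8 and NK cell markers gave 3 higher and 4 lower of 7 (3 and 4 adjusted over the list alone, 0.859). Eomes and Gzmm were higher and Cd8b1, a CD8 chain, fell by 1.25 (SE 0.16). Erythroid and platelet markers rose for 1 of 3 (1 adjusted over the list alone, 0.681). Median, mean and test differed in sign for helper lineage factors, follicular helper genes, chemokine receptors, CD8 and NK cell markers, erythroid markers and ribosomal protein genes. Fry passed for 19 of the 25 lists.

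**Figure D2:**
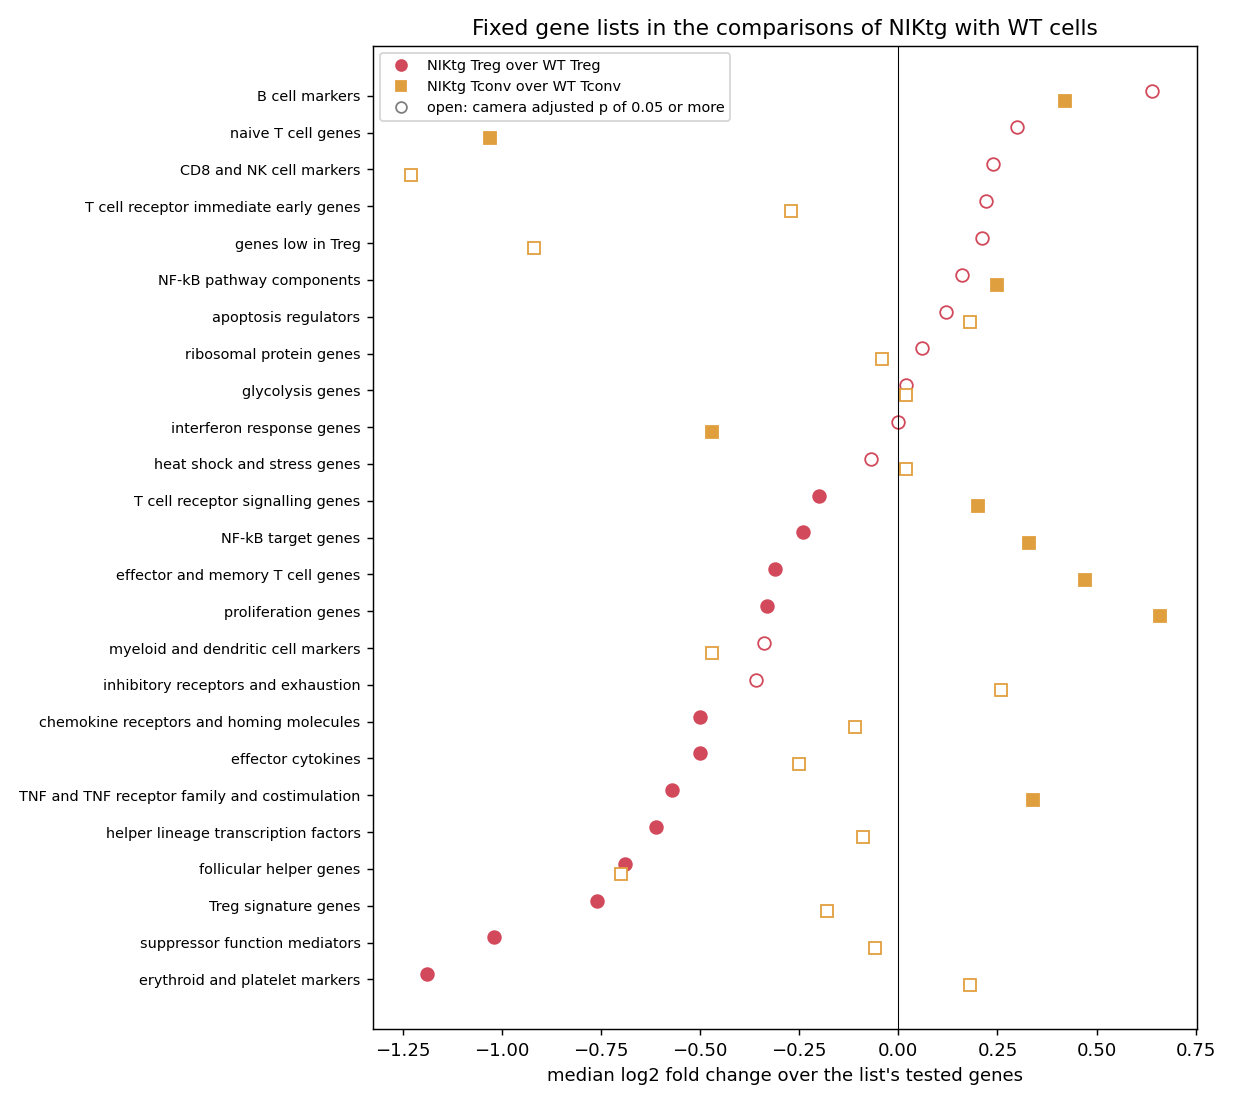
Median log2 fold change of the tested genes of each of the 25 lists (horizontal axis), for NIKtg Treg over WT Treg (circles) and NIKtg Tconv over WT Tconv (squares), filled where camera's adjusted p with its preset correlation was under 0.05. The 12 filled circles lie below 0, and 7 of the 9 filled squares lie above 0. With an estimated correlation 0 lists passed, the lowest adjusted p being 0.162 in Treg and 0.326 in Tconv.

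Genes called in both subsets more often moved in opposite directions than in the same one. Batf, a transcription factor of activated T cells, fell by 1.93 in Treg and rose by 1.83 in Tconv, and for Cxcr3 the difference between the NIK effects (Treg minus Tconv) was -4.25 (SE 0.31, adjusted p = 0.00028, limma interaction test, n = 2 arrays per group). Plac8 had the largest positive fitted difference, 5.90 (SE 0.54, adjusted p = 0.000537), followed by Tmem176b at 5.82 (SE 0.47), Myh7 at 5.67 (SE 0.36), Actn2 at 5.65 (SE 0.31) and Tmem176a at 5.02 (SE 0.39). Klrg1 (-5.87, SE 0.97), Gzmk (-5.70, SE 0.45), Tspan3 (-5.09, SE 0.30), Gzmm (-4.99, SE 0.42) and Scin (-4.75, SE 0.25) had the largest negative ones. Myh7, Gzmk and Scin were below detection on both arrays of at least 1 group, and Klrg1 on 1 array, so the size and rank of their values rest on the background. Nfkb2 and Eomes rose in both subsets. The effect of NIK differed between the subsets for 3106 of 7926 genes, 1826 with a higher value in Treg and 1280 with a lower one (58.8% higher). At least 2-fold differences were 715 higher and 756 lower, so the excess of higher values was absent there. Of 373 genes whose several probes all passed in 1 direction 38.6% were higher, against 58.8% for the full count of 3106 genes. That count was 2005 without NIKtg Tconv 1. Median centring moved the median of all genes from 0.149 to 0.255 in this comparison, a shift of 0.106.

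Of the genes called in both, 307 fell in Treg and rose in Tconv, against 96.7 for independent lists, and 331 rose in Treg and fell in Tconv, against 142. Both effects were upward for 71 genes, against 107, and downward for 86, against 129. The 2 comparisons have no array in common. Across genes, which are not independent replicates, the NIK effects in Treg and in Tconv correlated at a Pearson r of -0.265 and a Spearman rho of -0.38. The count of 638 fell to 203 without WT Treg 1, 227 without WT Treg 2, 276 without NIKtg Treg 1, 344 without WT Tconv 1, 271 without NIKtg Tconv 1 and 385 without NIKtg Tconv 2. The 157 genes of equal direction became 75 without WT Treg 1, 70 without WT Treg 2, 94 without NIKtg Treg 1 and 89 without NIKtg Tconv 1. No gene called with the full set of arrays changed sign when an array was left out. A called difference already exceeds the spread between replicates, so this was likely beforehand and adds little on direction.

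**Figure D3:**
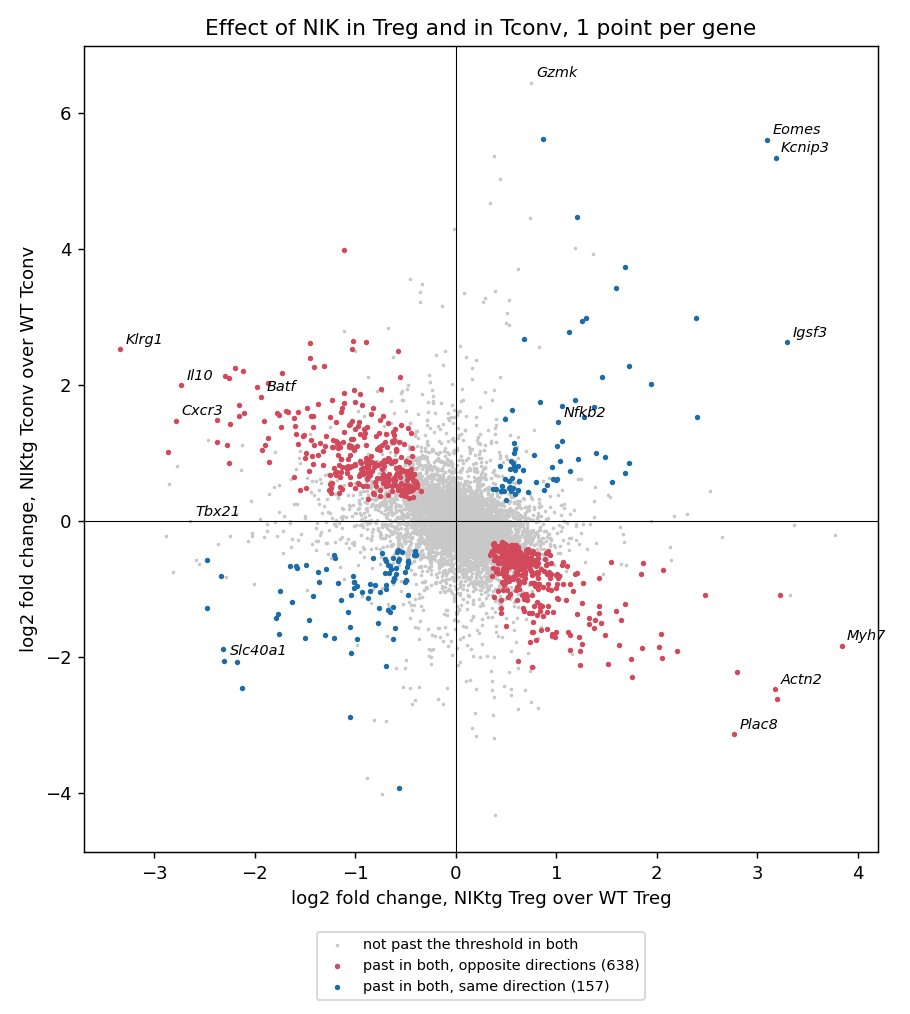
Log2 fold change of each of 7926 genes in Treg (horizontal axis) and in Tconv (vertical axis), NIKtg over WT, 1 point per gene. Red points are the 638 genes past the threshold in both with opposite signs, mainly in the upper left and lower right, and blue points the 157 with the same sign.

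By list, proliferation genes had 15 of 24 members lower and 1 higher in the interaction (16 and 2 adjusted over the list alone), for example Top2a at -2.37 (SE 0.21). NF-kB target genes had 17 lower and 3 higher of 31 (18 and 3 adjusted over the list alone), for example Ccl4 at -4.33 (SE 0.36) and Gadd45b, a stress-induced regulator, at -1.79 (SE 0.15). TNF family genes had 13 lower and 1 higher of 20 (14 and 1 adjusted over the list alone), for example Tnfsf11 at -2.12 (SE 0.22). T cell receptor signalling genes had 9 lower and 1 higher of 20 (9 and 1 adjusted over the list alone), and chemokine receptors 9 lower and 4 higher of 14 (9 and 4 adjusted over the list alone), for example Cxcr5 at -3.58 (SE 0.20). Camera adjusted p values were 7.38e-06, 7.38e-06, 2.49e-05, 0.00125 and 0.00883, and with an estimated correlation the adjusted p of each was 0.243. Effector and memory genes had 12 lower and 3 higher of 25 (14 and 3 adjusted over the list alone, camera adjusted p = 0.000161), and naive T cell genes 12 higher and none lower of 17 (13 and 0 adjusted over the list alone, 0.000215), with Ccr7 at 2.65 (SE 0.34). Treg signature genes had 13 lower and 6 higher of 26 (14 and 7 adjusted over the list alone, 0.00883), with Socs2 at 2.44 (SE 0.40). With an estimated correlation the adjusted p values were 0.333, 0.334 and 0.383. Helper lineage factors had 6 lower and 3 higher of 15 (7 and 3 adjusted over the list alone, camera adjusted p = 0.0386, or an adjusted p of 0.243 with an estimated correlation), a call lost without NIKtg Tconv 2 (0.0519), NIKtg Treg 1 (0.0563), NIKtg Treg 2 (0.0608) or WT Treg 1 (0.0549). Fry passed for 19 of the 25 lists. Median, mean and test differed in sign for effector cytokines, apoptosis regulators, B cell, myeloid, and CD8 and NK cell markers, which did not pass camera.

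The last comparison asked how NIKtg Treg differed from NIKtg Tconv. Foxp3 was 6.73 higher in NIKtg Treg (SE 0.33, adjusted p = 2.58e-05, n = 2 arrays per group), Nrp1 4.92 (SE 0.25), Gpr83 4.89 (SE 0.33) and Ecm1 4.73 (SE 0.29), and Il2ra, the high-affinity interleukin receptor chain, was at least 38.8-fold higher. Gzmk was at least 60.2-fold lower in NIKtg Treg, Esm1 at least 24.3-fold, Itgad at least 14-fold and Crtam, a receptor of cytotoxic lymphocytes, at least 11.3-fold, and Gzmm was lower too (-4.78, SE 0.30). Il10 was at least 2.77-fold lower in NIKtg Treg than in NIKtg Tconv, the reverse of the WT difference, in which it was at least 2.88-fold higher in Treg (adjusted p = 0.00536). In total 3165 genes differed (limma), 1828 higher and 1337 lower (57.8% higher), while at least 2-fold differences were 471 higher and 471 lower, and of 380 genes whose several probes all passed in 1 direction 44.5% were higher. The count was 2089 without NIKtg Treg 1, 1908 without NIKtg Tconv 1 and 2103 without NIKtg Tconv 2.

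Treg signature genes were higher for 19 and lower for 2 of 26 (19 and 2 adjusted over the list alone), suppressor mediators for 8 and 1 of 10 (8 and 1 adjusted over the list alone) and B cell markers for 7 and 1 of 10 (8 and 1 adjusted over the list alone), with Cd79b at 2.84 (SE 0.11). Interferon response genes were higher for 11 and lower for 2 of 21 (12 and 2 adjusted over the list alone), with Igtp at 2.27 (SE 0.17). Proliferation genes were lower for 15 and higher for 1 of 24 (16 and 1 adjusted over the list alone), with Top2a at -1.96 (SE 0.15), and effector and memory genes lower for 15 and higher for 2 of 25 (16 and 2 adjusted over the list alone), with Anxa2 at -2.21 (SE 0.14). T cell receptor signalling genes were lower for 9 and higher for 1 of 20 (9 and 1 adjusted over the list alone), and CD8 and NK cell markers lower for 4 and higher for 1 of 7 (5 and 1 adjusted over the list alone). Camera adjusted p values in that order were 3.09e-07, 0.015, 0.00766, 0.0379, 7.44e-07, 1.71e-05, 0.000967 and 0.0101. With an estimated correlation the adjusted p values were 0.244, 0.244, 0.312, 0.634, 0.244, 0.312, 0.244 and 0.244. With bounds the medians of the proliferation and the effector and memory lists changed from -0.78 to -0.65 and from -0.98 to -0.82. The interferon list was lost without NIKtg Tconv 2 (adjusted p = 0.0797) or NIKtg Treg 1 (0.0843), with the mean of probes (0.102), median centring (0.0755) and the replicate block (0.0618). Fry passed for 19 lists. Median, mean and test differed in sign for genes low in Treg, the TNF family, effector cytokines, inhibitory receptors, glycolysis genes and apoptosis regulators, which did not pass camera.

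Of the 1906 genes that differed between WT Treg and WT Tconv, 521 (27.3%) differed in the same direction in NIKtg cells and 504 in the opposite direction. The exact 95% interval of that share was 25.3 to 29.4 with genes taken as independent, which they are not, and with 1 array left out the share ran from 21.6% (without NIKtg Treg 1) to 39.7% (without WT Tconv 1). The interaction test passed for 1283 of the 1906 genes (67.3%), against 39.2% of all 7926 genes. Choosing genes by the WT difference raises that share, since the interaction contains this difference from the same arrays. For independent lists, 203 genes higher in both and 173 lower in both would be found, against 338 and 183, and 149 and 236 of opposite direction, against 211 and 293. Over the 1906 genes the slope of the NIKtg on the WT difference was 0.224, and with the comparisons exchanged, over the 3165 genes, it was 0.108. Selecting genes by the first comparison lowers such a slope. Foxp3, Itgae, Ctla4 and Nt5e were higher in Treg in both, at 6.73, 3.84, 1.98 and 1.19 in NIKtg cells, whereas Cxcr5 was 2.03 higher in WT Treg (SE 0.14) and 1.55 lower on the log2 scale in NIKtg Treg (-1.55, SE 0.14).

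Different probes of a gene did not always give the same sign. Of 2087 genes with several kept probes, 855 had a probe called for NIK in Treg, and 32 of these had probes called in opposite directions, against 33 of 1023 for NIK in Tconv, 116 of 1376 for the interaction, 2 of 635 for WT Treg against WT Tconv and 119 of 1399 for NIKtg Treg against NIKtg Tconv. Some probe of the other sign, called or not, was present for 40.4%, 27.2%, 36.8%, 15.6% and 35.7% of these genes. Besides Cd247, each other kept probe had the opposite sign to the brightest for Fas, Lyz2 and Rpl29 in the Treg comparison.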

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

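The tests of array brightness, of other probes, of NIKtg Tconv cells in the NIKtg Treg gate and of macrophage RNA in this part were chosen only after the result was seen, while the test of Treg cells in the WT Tconv gate was set before its result was seen. The brightness test of opposite effects was changed more than once after its values were seen. Its limit was changed first, and its genes were then chosen anew, because called genes are also selected for a small spread between replicates. The limit for macrophage RNA was tightened after its first value was seen, by also asking that the myeloid list fixed in advance pass camera, and the brightness test of macrophage transcripts was moved to that list. The test of NIKtg Tconv cells replaced one that set the fall of the genes against that of Foxp3.

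The difference between NIKtg and WT cells was not the same in Treg and Tconv, by the interaction test, for 3106 of 7926 genes (39.2%). The test also passed for 159 of the 209 genes that the rule named in the NIK comparisons. Most of these were chosen by their NIK effects on the same arrays, which raises their share, so it adds no support. The largest differences (Treg minus Tconv, log2) were 5.90 for Plac8, 5.82 for Tmem176b, 5.67 for Myh7, 5.65 for Actn2 and 5.02 for Tmem176a, and -5.87 for Klrg1, -5.70 for Gzmk, -5.09 for Tspan3, -4.99 for Gzmm and -4.75 for Scin, of which those of Myh7, Gzmk, Scin and Klrg1 rest in part on values below detection. Median differences of the lists past camera were 1.36 for naive T cell genes, -0.43 for T cell receptor signalling genes, -0.47 for helper lineage transcription factors, -0.76 for Treg signature genes, -0.78 for NF-kB target genes, -0.91 for effector and memory genes, -1.03 for the TNF family, -1.07 for proliferation genes and -1.12 for chemokine receptors. Over the 25 lists the lowest adjusted p with an estimated correlation was 0.243 for this difference. Among 707 probes without a gene name, which no gene count uses, 127 (18%) passed for NIK in Treg and 200 (28.3%) for NIK in Tconv, against 21.3% and 29.7% of the named probes.

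The opposite direction of NIK effects in Treg and Tconv (638 genes) was weighed against the technical explanations named here, which are not all that could apply. The labels do not say that replicates came from separate animals, so a technical difference between the groups' samples was not weighed and cannot be told apart. The NIKtg arrays were dimmer than WT in Treg (ratio of mean intensity 0.826) and brighter in Tconv (1.14), an order that 307 of these genes followed and 331 reversed. Over 1417 genes of opposite direction chosen by their group means alone, the slope on brightness was 0.116 log2 units per doubling within groups against 2.52 between groups, and the NIKtg Tconv replicates, which differed more in brightness (1.26), shifted by -0.09 (quartiles -0.24 and 0.04, limit 0.42), against brightness. The WT Tconv replicates (1.2) shifted by 0.17, a slope of 0.667, with an upper quartile of 0.34 above their limit of 0.33, and although the NIKtg Treg replicates shifted as much (0.18, quartiles -0.01 and 0.39) at nearly equal brightness (1.03), the limit asked for both Tconv groups, so brightness stays open. Other probes of the same genes, detected on all 8 arrays, had both signs of the brightest probe for 109 of 147 (74.1%, exact 95% interval 66.3 to 81 with probes taken as independent). This argues against probe-specific change as the whole cause, for the 119 genes with such probes. In sign alone, other probes agreed for 79.1% of calls for NIK in Treg and 87.1% in Tconv, against 94.3% for the WT subsets, so probe-specific change in part stays open. NIKtg Tconv cells in the NIKtg Treg gate could only bring values between those of WT Treg and NIKtg Tconv, while 563 of the 638 genes (88.2%) lay beyond NIKtg Tconv in NIKtg Treg, past the threshold, which argues against such cells as the whole cause, while a response to NIK that differs between subsets also stays open and was not tested apart from its cause.

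Macrophage transcripts were lower on the NIKtg arrays of both subsets, across a list of 27 markers written after some of the values were seen. Of 20 tested, 16 (80%) had lower values in both, though 10 were detected on no NIKtg array, and with markers at their bounds the medians were -0.62 in Treg and -0.34 in Tconv, with Slc40a1, the iron exporter of red pulp macrophages, at -2.30 and -2.06. RNA of macrophages in the WT gates (GFP-negative and Thy1.1-positive, against GFP-positive and Thy1.1-negative for NIKtg) could account for this, although cells without Thy1 should fall outside a Thy1.1-positive gate. Of the 3 markers with the highest probe signal in WT, which T cells also express, Ctsb was lower in both (-0.75, adjusted p = 0.006, and -0.19, adjusted p = 0.23) and Ctss (0.53 and -0.06) and Cst3 (-0.34 and 0.28) were not. Signals of different probes do not rank the abundance of their transcripts. The myeloid list fixed in advance missed the threshold (camera adjusted p = 0.102 and 0.144), so the tables do not decide. In Tconv, where the NIKtg arrays were the brighter ones, the 9 markers of that list had a median of -0.28 with bounds (quartiles -0.53 and -0.10). This cannot decide on brightness, since the direction in which brightness moves these markers after quantile normalization was not tested.

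Foxp3 and 9 other Treg signature genes fell on the NIKtg Tconv arrays. Treg cells in the WT Tconv gate could bring such transcripts, and Foxp3's own excess would need 2.15% of WT Treg signal. Of the 9 other genes, 8 would need over 2 times that share, with a median of 10.5%. Their shares ran from 4.23% (Ikzf2) to 37.6% (Fgl2), with Cish at 9.98%, Nrp1 at 10.2%, Gpr83 at 10.5%, Izumo1r at 12.7% and Icos at 36.7%. This argues against 1 share of RNA from cells with the Foxp3 level of sorted WT Treg as the whole cause. Tconv were sorted as reporter-negative, so Treg left in that gate may be selected for low Foxp3, and 1 share of such cells stays open. Icos, Fgl2 and Socs2 are also expressed by activated Tconv. A part of Foxp3's change from Treg cells stays open, as does an effect of NIK on the 9 other genes.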

How the results depend on the processing

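Calls among genes with several probes were chosen as a test only after seeing that probes disagreed. The other settings were planned. Of the counts and shares, 140 stayed within 1.5 times (shares within their interval) and 47 moved. Named genes kept their side of the threshold in 11260 comparisons of settings, gained it in 296, lost it in 279 and reversed in 1. Lists kept it in 2317, gained it in 73, lost it in 105 and reversed in 0, and the correlation across genes kept its sign in 22 of 22. The reversal was Rps4x in NIKtg Treg minus NIKtg Tconv, at -0.49, which gave 0.08 with median centring (adjusted p = 0.661, limma), and missed the threshold without NIKtg Treg 1 (-0.39, adjusted p = 0.0764) and without NIKtg Tconv 2 (-0.41, adjusted p = 0.0795), and the cause was not tested.

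With a 2-fold minimum, 422 (Treg) and 661 (Tconv) genes differed between NIKtg and WT. With every probe as its own feature there were 2434 calls for NIK in Treg, 4668 for the interaction and 1047 of opposite direction, and 44% of the Treg calls were higher against 52.4%. Without a filter 418 genes had opposite directions, and among probes detected on all 8 arrays 24.1% of the WT subset difference was kept in direction. The causes were not tested. Among genes with several probes, calls by every probe against the brightest probe numbered 133 and 405 (NIK in Treg), 288 and 661 (NIK in Tconv), 373 and 833 (interaction), 221 and 478 (WT subsets), and 380 and 848 (NIKtg subsets), lower than over all genes because only genes with several probes entered, and lower by every probe because each probe had to pass. The share of higher calls by every probe turned in each comparison, to 28.6% from 52.4%, 58.7% from 42.9%, 38.6% from 58.8%, 66.1% from 46.3% and 44.5% from 57.8% over all genes, in the same order. By the brightest probe of the same genes with several probes it was 49.4%, 46%, 54.4%, 49.8% and 55.3%, so for NIK in Treg the choice of genes alone had turned it. Over all genes the share for NIK in Treg was also 47.3% with the mean of probes and 49.6% in the fit to only the groups compared.

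Leaving out 1 array gave 506 to 1624 genes for NIK in Treg, 964 to 2531 for NIK in Tconv, 2005 to 3109 for the interaction, 994 to 2013 for WT subsets, 1908 to 3185 for NIKtg subsets, 203 to 685 genes of opposite and 70 to 165 of equal direction, and 21.6 to 39.7% kept. The lone array of a group is then assumed to vary like the other groups, with 3 residual degrees of freedom. Of the named calls, 58 of 86 (NIK in Treg), 83 of 97 (NIK in Tconv), 86 of 94 (interaction), 65 of 86 (WT subsets) and 87 of 94 (NIKtg subsets) passed with each array left out in turn. For the gene lists 10 of 12, 6 of 9, 8 of 9, 10 of 15 and 7 of 8 did so.

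The labels do not say what same-numbered arrays share. Their deviations correlated at -0.0189 between the Treg groups, 0.0167 between the Tconv groups, 0.136 between the WT groups and 0.0214 between the NIKtg groups, and at -0.0135 (WT Treg, NIKtg Tconv) and 0.143 (NIKtg Treg, WT Tconv). With the replicate block the counts were 1586, 2363, 3089, 1898 and 3176 in the same order, and the consensus correlation by number was -0.0203. That block ended the list calls of glycolysis genes (adjusted p = 0.0647) and genes low in Treg (0.0678) between WT subsets and of interferon response genes between NIKtg subsets (0.0618). The fit to only the groups compared gives no value for the interaction, and the slide block was not run. For signal over background, between 38.2 and 42% of probes per array were detected, and for genes below detection in a group only bounds can be given.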

Other observations

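The sets of genes in this part were put together only after the result was seen. Some of their genes were also named by the rule fixed in advance, and the fold changes come from the planned comparisons.

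The class II genes H2-Eb1 (2.40 in Treg, 1.53 in Tconv) and H2-Aa (1.69, 0.70) rose in both, as did the invariant chain Cd74 (1.05, 1.70) and H2-Oa (0.68, 2.68) and H2-Ob (0.91, 0.54), subunits of a class II loading regulator. H2-DMb1, a subunit of the loading catalyst, rose by 1.14 in Treg and was lower in Tconv (adjusted p = 0.00357), and H2-DMa gave 0.55 (adjusted p = 0.099, limma) and -1.12 (adjusted p = 0.00661). The 4 kept probes of H2-Ab1 were not alike, with 1.73, 1.58, 1.98 and 0.02 in Treg and 0.86, 0.37, 0.41 and 1.54 in Tconv. Of the B cell genes, Cd79b and Fcmr fell in both comparisons, though the other kept probe of Cd79b read -1.03 in Treg and 0 in Tconv. Cd22 was at least 1.65-fold lower in Treg (adjusted p = 0.0553, not past the threshold) and rose by 2.79 in Tconv.

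Of genes of the muscle sarcomere, Actn2 rose by 3.18 with NIK in Treg and fell by 2.47 in Tconv. Myh7 was at least 7.64-fold higher in Treg and lower in Tconv (adjusted p = 0.0023), and Tnni3 was at least 5.58-fold higher in Treg and did not pass in Tconv (adjusted p = 0.066). Ttn, the giant sarcomere protein, rose by 1.13 in Treg and was higher in Tconv (adjusted p = 0.00043), and Tpm1 gave -0.09 (adjusted p = 0.58) and 0.18 (adjusted p = 0.23). Myh7 and Tnni3 were below detection on both WT Treg and both NIKtg Tconv arrays and detected on both NIKtg Treg and both WT Tconv arrays.

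The Y-linked genes Eif2s3y, Kdm5d and Uty were detected on 8 of 8 arrays, and the Xist probes on 0 of 8.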
